A study of Mus musculus with 2 samples.

How the data were processed

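One series of mouse TH2 cells was analysed, with 1 ChIP library (TY1 antibody, TY1-tagged PPARγ expressed from a retrovirus) and 1 input library. The input served the authors as background for peak calling, and no values of its own were used here. Per the labels' protocols, cells were transduced on days 1 and 2 and harvested on day 4. The series text gives 13.23M single-end reads of 100 bp, whereas the labels' extract protocol gives 50 bp; which is right was not settled, and no value depends on it. The series text also states that the experiment was repeated and that only 1 replicate was used.

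Per the series text and the submitters' processing notes, reads were aligned to mm10 with Bowtie2, tags with a unique position were kept, and peaks were called with HOMER; versions were not given in the sources used here. Per the file headers, peaks were called in the transcription factor style with a fragment length and peak size of 172 bp, at least 344 bp between peaks and at most 1 tag per position. A false discovery rate of 0.001 corresponded to 8 tags. Each peak needed at least 4 times the tag density of the input and of the surrounding 10000 bp, each with a Poisson p of 1e-04. Unique alignment leaves out sequence that recurs exactly elsewhere, and subtraction of the input removes regions of high background. The score column of the deposited file holds the value 1 in each row: the header names 15 columns and the rows hold 6. The score therefore ranks no peak, and the planned tests by score were not run.

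Peak coordinates were read as deposited and are printed counting from 1. All peaks lay within the chromosome lengths of GRCm38, the assembly that mm10 names. Genes and transcripts came from the GENCODE vM21 annotation of that assembly, sequence and repeat masking from its reference FASTA. The class of a peak was that of its centre, in the order promoter, exon, intron, intergenic, over all 55413 annotated genes, so that a promoter may belong to another or a noncoding transcript. Distances run from the peak centre to the nearest TSS of a protein-coding gene, alternative start sites included, and gene assignment used the nearest such TSS within 100 kb. Location was tested against 1000 sets of random regions of the same chromosome and width outside assembly gaps (permutation of region positions, two-sided empirical p). Motifs were searched on both strands in 200 bp windows around peak centres and in 10 background windows per peak matched on GC content in 2% bins and on promoter class, with Fisher's exact test, two-sided. Central enrichment compared matches within 50 bp of the centre with those at 300 to 500 bp (exact binomial test). 36 motifs, 12 repeat spacings and all 8-mers each formed a family. DR1 was AGGTCANAGGTCA with up to 2 mismatches in its 12 fixed bases.

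The 19 gene lists, with 589 of 591 symbols matched to the annotation, were written before the data were examined, as were the motifs, the tests and the naming rule. Genes with a peak were counted in each list and compared with 10000 random lists of protein-coding genes matched on territory length, the sequence nearest to a gene's TSS within 100 kb, in 20 bins (permutation of list membership, two-sided empirical p, smallest possible 0.0002). Some genes stand in more than 1 list: TH2 and regulatory T cell lists share 3, TH2 and TH17 lists 2, and such genes were left out of the tests between helper subset lists (Fisher's exact test, two-sided). No data on open chromatin were used here, so a list of active genes can stand out for accessibility. P-values were adjusted within each family by the Benjamini-Hochberg method with a threshold of 0.05. Intervals are exact binomial (Clopper-Pearson) at 95%, and those of odds ratios are Wald intervals; all cover counting error only.

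Named are up to 8 genes per list with the peak nearest to the TSS, the 15 genes with the most peaks, a fixed set of TH2, TH1 and PPAR target genes with or without peaks, the 5 most enriched and 3 most depleted motifs and the 3 leading 8-mers. A further part of the rule, genes of the peaks with the highest score, could not be applied. A few genes that the rule names are not reported here. The location, motif, 8-mer and gene list tests were tried on simulated data, and the other tests were not. With random positions 0 of 4 location classes and 0 of 36 motifs passed, and planted sites gave 6 of 6 planted 8-mers. A planted gene list was called in 20 of 20 runs, with 1 of 360 other list tests called.

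Alternatives covered the annotation and promoter width, window size, background, mismatches, flanks, 7-mers, the rule that assigns peaks to genes and subsets of peaks. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.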

Results

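PPARγ, a ligand-activated nuclear receptor best known for its part in fat cell differentiation, was mapped across the genome of mouse TH2 cells, the helper T cells of type 2 immunity. Naive CD4 T cells of the C57BL/6J strain were activated and polarised in culture, and they received retrovirus carrying PPARγ with a TY1 epitope tag on days 1 and 2. Chromatin was prepared on day 4 and precipitated with an antibody against the tag, so the map describes the introduced receptor. It rests on 1 ChIP library set against 1 input library, with no replicate. Every p-value here takes peaks, sequence windows or genes as its units and describes this peak list, not the spread between cultures. Per the file header, the library held 10229438 uniquely mapped tags, of which 54617 (0.53%) lay in peaks, on average 21.5 tags per peak. Of 3239 putative peaks, 682 (21.1%) were removed against the input and 20 against local signal, which left 2537 peaks of 173 bp each. The rows of the file hold no tag count or strength for single peaks, so each peak counted once.

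The first comparison asked where the receptor sat relative to genes. PPARγ peaks fell in promoters and introns more often than random regions did, and in intergenic sequence less often. Promoters, taken as 1000 bp upstream to 100 bp downstream of a transcription start site (TSS), held 204 peak centres, or 8.04% (exact 95% binomial interval 7.01 to 9.17). Random regions from the same chromosomes gave 2.61% ± 0.318 (SD over 1000 sets), a 3.08-fold difference. Introns held 52.4% of the peaks against 43.5% of random regions, and intergenic sequence 36.0% against 50.1% (adjusted p = 0.00266 for each of these 3 classes by permutation of region positions, the smallest that the random sets can give). The exon share, 3.55%, was not told apart from the random 3.78% (adjusted permutation p = 0.58), although it lay below random when protein-coding genes alone were used (log2 fold −0.39, adjusted p = 0.044). Most peaks were far from promoters: the median distance to the nearest protein-coding TSS was 23.5 kb (quartiles 6.64 and 63.3 kb), with 199 peaks (7.84%) within 1 kb and 2124 (83.7%) within 100 kb. These 2124 peaks were assigned to 1679 of 21851 protein-coding genes (7.68%). Repeat-masked sequence held 16.2% of the peak centres and 35.8% of the matched background windows.

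**Figure D1:**
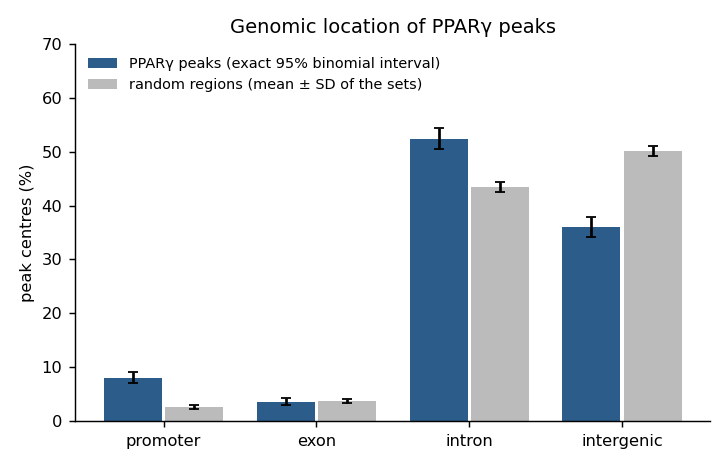
Share of peak centres in each annotation class (y axis, percent) for the 2537 PPARγ peaks (blue, with exact 95% binomial intervals) and for 1000 sets of random regions (grey, mean ± SD). The promoter bar stands at 8.04% against 2.61% and the intergenic bar at 36.0% against 50.1%.

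The next comparison asked which sequences mark the peaks. The DR1 element, a direct repeat of AGGTCA with a 1 bp spacer that PPARγ binds together with its partner RXR, was the most enriched of 36 motifs. With up to 2 mismatches allowed, 502 of the 2537 peaks held a DR1 match (19.8%, exact 95% interval 18.3 to 21.4), against 2.53% of 25370 background windows matched for GC content and promoter class (log2 odds ratio 3.25 ± 0.09 SE, adjusted p = 1.42e-225, Fisher's exact test). A scrambled DR1 of the same composition occurred in 2.33% of peaks and 2.51% of background windows (exact adjusted p = 0.68). AP-1, the site of FOS and JUN family factors induced by T cell activation, came second at 17.9% against 3.16% (log2 odds ratio 2.74 ± 0.09 SE, exact adjusted p = 1.7e-161). The CEBP site (2.28 ± 0.64), the ROR site, which shares the AGGTCA core of DR1 (2.27 ± 0.19), and the AP-1 and IRF composite site of activated T cells (2.09 ± 0.17) completed the 5 most enriched. The CEBP value rested on 7 peaks and was 0.57 against shuffled peak sequence (exact adjusted p = 0.39) and 1.12 in the last 1269 peaks of the file (adjusted p = 0.414). Of the 89 peaks with a ROR site, 48 also held DR1, and among peaks without DR1 the ROR value was 1.54 ± 0.25. The ROR site as searched, AWNTRGGTCA, takes in the extended PPAR half-site AWCTRGGTCA, so the 2 cannot be told apart. That half-site, with 1 mismatch allowed, had a log2 odds ratio of 1.44, and 1.11 among peaks without DR1.

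Sites of other T cell factors had lower odds ratios. The sites of MAF (9.38% against 3.33%), ETS factors (4.02% against 1.74%), RUNX factors (4.65% against 2.29%) and STAT5 (5.83% against 2.97%) had log2 odds ratios of 1.59, 1.25, 1.06 and 1.02. The MAF site as searched, TGCTGASTCA with 1 mismatch allowed, contains the AP-1 site TGASTCA, so its value is not independent of AP-1. The site of GATA factors, the family of the TH2 regulator GATA3, was present in 16.2% of peaks and 12.3% of background windows (log2 odds ratio 0.46 ± 0.08 SE, exact adjusted p = 1.96e-07). Its log2 odds ratio was 0.68 in the first 1268 peaks of the file and 0.23 in the other 1269, where it did not pass the threshold (exact adjusted p = 0.0904). The STAT6-type site (0.31, exact adjusted p = 0.082), the T-box site (0.22, adjusted p = 0.63) and the NFAT site (−0.21, adjusted p = 0.13) did not pass the threshold. The STAT6-type site did pass against shuffled peak sequence (0.76, exact adjusted p = 2.8e-05) and in 400 bp windows (0.39, adjusted p = 0.0026), and the NFAT site was depleted in 100 bp windows (−0.42, adjusted p = 0.036). Depleted were the sites of YY1 (0.749% against 2.02%, log2 odds ratio −1.41) and NFY (6.15% against 8.43%, −0.49), which with NFAT had the lowest odds ratios. Against shuffled peak sequence the YY1 value was 0.28 (exact adjusted p = 0.45). The background windows were not matched on repeats, so a depletion against them cannot be told apart from fewer repeats in the peaks.

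DR1 matches were concentrated at the peak centres. Within 50 bp of the centre there were 1.46 DR1 matches per kb, against 0.186 per kb at 300 to 500 bp from the same centres, a 7.83-fold difference (log2 ratio 2.97 ± 0.13 SE), and the scrambled DR1 gave 0.916-fold (exact binomial adjusted p = 0.7). AP-1 matches were 3.98-fold and ROR matches 6.07-fold denser at the centre, and GATA matches 1.29-fold. The best DR1 match lay a median of 32 bp from the centre. Its spacer base was adenine in 52.8% of the peaks with a DR1 match and in 21.0% of the background windows with one. The base directly upstream of the repeat was thymine in 46.7% against 14.4% (adjusted p = 2.3e-31, Fisher's exact test chosen after the enrichment was seen).

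**Figure D2:**
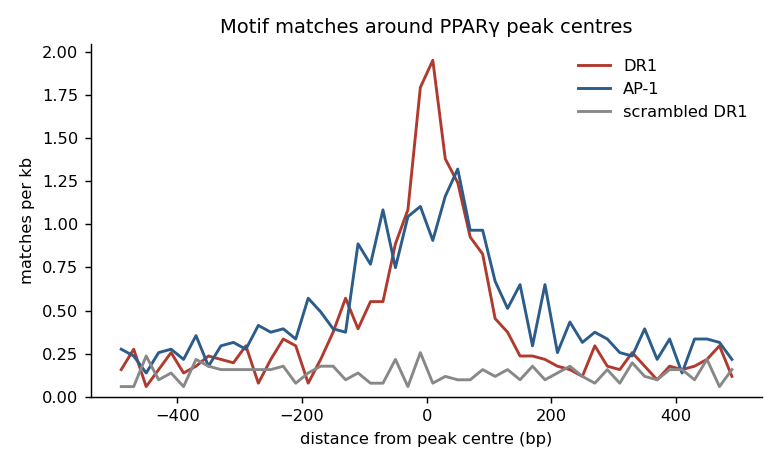
Motif matches per kb (y axis) in bins of distance from the PPARγ peak centre (x axis, bp), summed over 2537 peaks, for DR1 (red), AP-1 (blue) and the scrambled DR1 (grey). DR1 reaches 1.95 matches per kb next to the centre and AP-1 1.32 in the bin 50 bp from it, while the scrambled sequence stays at or below 0.256.

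The spacing of the repeat set DR1 apart from other arrangements of the same core. DR1 was 7.81-fold more frequent in peaks than in background, while the other 11 direct and inverted repeats lay between 1.29-fold for DR0 and 1.95-fold for DR6. All 12 arrangements passed the threshold with 2 mismatches allowed and 5 passed with 1 mismatch, where DR1 reached 18.95-fold (6.42% against 0.339%) and the others 0.814-fold (DR0) to 6.67-fold (IR3). In the last 1269 peaks of the file, adjusted over the 36 motifs, DR0, DR4, DR5, IR0, IR1 and IR3 did not pass with 2 mismatches. The 2035 peaks without a DR1 match were also set against background windows without one. There DR0, DR4, DR5, DR7 and IR1 did not pass (exact adjusted p = 0.14 to 0.47 over the 36 motifs). Among 32861 8-mers tested without reference to known motifs, 660 were enriched and 416 depleted. The background was not matched on repeats, which held 35.8% of its centres and 16.2% of the peak centres. Depletion of an 8-mer therefore cannot be told apart from fewer repeats in the peaks. The 3 leading enriched 8-mers were AAAGGTCA (8.71% against 1.11%), ATGACTCA (6.54% against 0.773%) and CAAAGGTC (6.07% against 0.788%). AAAGGTCA joins the last base of the upstream DR1 core to the spacer and the downstream core. ATGACTCA is an AP-1 site, and CAAAGGTC spans the DR1 spacer.

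**Figure D3:**
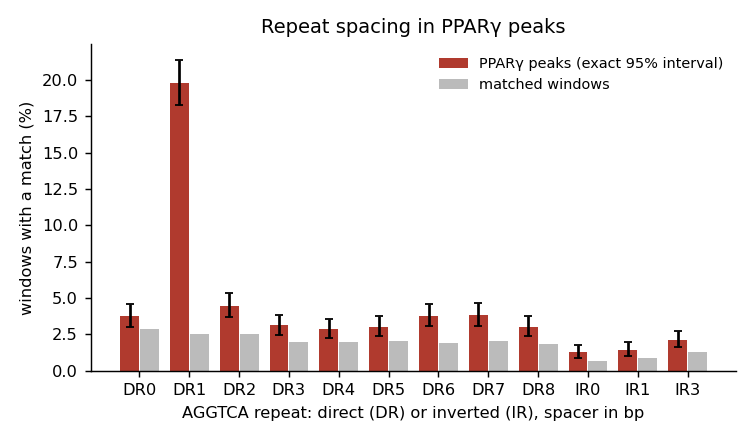
Share of windows with a match (y axis, percent) to AGGTCA repeats of each arrangement (x axis, direct repeats DR0 to DR8 and inverted repeats IR0, IR1 and IR3), in PPARγ peaks (red, exact 95% interval) and matched background windows (grey). DR1 stands at 19.8% against 2.53%; no other arrangement exceeds 4.45% of peaks.

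Peaks were then set against 19 gene lists. Genes of fatty acid oxidation stood furthest above expectation: 21 of 44 had a peak, where territory-matched random lists gave 2.88 (7.30-fold, adjusted permutation p = 0.00076). The fold depended on the setting, from 5.065 without DR1 peaks to 16.3 with DR1 peaks alone. Peaks lay at the start sites of genes for several steps of the pathway. The peak nearest to Slc25a20, the mitochondrial carnitine and acylcarnitine carrier, was centred 1 bp from its TSS (chromosome 9, 108662011 to 108662183, mm10) and held the DR1 match AGGTGAAAGGTCG. Promoter peaks also lay 123 bp from the thiolase gene Acaa2 and 134 bp from the isomerase gene Eci2. All 3 genes of the electron transfer flavoprotein route, which passes electrons from acyl-CoA dehydrogenases to the respiratory chain, had a peak near the start site. Promoter peaks lay 162 bp from Etfa and 278 bp from Etfb. The Etfdh peak (chromosome 3, 79628287 to 79628459, with the DR1 match AGGTTAAAGGTCA) lay 324 bp downstream of its nearest TSS, in the promoter of another transcript. The very long chain acyl-CoA dehydrogenase gene Acadvl had an intronic peak at 325 bp. Cpt1a, the gene of the enzyme that commits fatty acids to mitochondrial import, had 2 intronic peaks, the nearer at 2.37 kb, neither with a DR1 match. Pdk4, a pyruvate dehydrogenase kinase, had 2 intergenic peaks, the nearer at 8.92 kb.

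Known PPAR targets in lipid storage held peaks at 10 of 51 genes against 3.96 in random lists (2.52-fold, adjusted permutation p = 0.0195). This call was lost without chromosomes X and Y, by gene body and without DR1 peaks (adjusted permutation p = 0.062, 0.092 and 0.31). The excess was larger within 10 kb (4.35-fold) and with DR1 peaks alone (6.14-fold, adjusted permutation p = 0.0038 for each). Plin2, which encodes a lipid droplet coat protein, had 4 intergenic peaks, the nearest at 1.04 kb, and 2 of them held DR1 matches. Hilpda, which encodes an inhibitor of triglyceride breakdown, had 3 peaks (2 with DR1), the nearest at 1.42 kb. The triglyceride synthesis gene Dgat1 had a promoter peak at 343 bp. Angptl4, which encodes a lipoprotein lipase inhibitor, had 2 peaks without DR1, the nearer at 2.38 kb in an intron. The lipase gene Lipe had an intronic peak at 2.72 kb. The fatty acid binding protein gene Fabp4 had an intergenic peak 3.69 kb upstream (chromosome 3, 10212184 to 10212356) with the DR1 match AGGTCACAGTTTA. Intronic peaks with DR1 lay in Pck1, a gene of gluconeogenesis and glyceroneogenesis, at 4.52 kb, and in the acyl-CoA synthetase gene Acsl5 at 7.26 kb. Cd36, which encodes a fatty acid transporter, had no assigned peak, and its nearest peak was 3496 kb away. Cholesterol and LXR pathway genes had 6 of 24 against 2.09 (2.87-fold, adjusted permutation p = 0.059). Within 10 kb 0 of 24 had a peak, and the first 1268 peaks of the file gave 0.834-fold. Abca1, a cholesterol exporter gene, held 3 peaks, the nearest at 41.0 kb, and 2 of them held DR1.

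The culture was polarised to TH2, and the TH2 list held peaks at 15 of 41 genes against 3.62 in random lists (4.14-fold, adjusted permutation p = 0.00076). The nearest peaks were at the promoter of Ccr8, a chemokine receptor gene, at 752 bp, upstream of the IL-2 receptor gene Il2ra at 1.33 kb with a DR1 match, and 3.62 kb from Cd200r1. The retinoic acid receptor gene Rara had an intronic peak with DR1 at 3.95 kb. Intronic peaks lay 11047 bp into Gata3 (chromosome 2, 9867467 to 9867639, centred in repeat-masked sequence) and 13.8 kb into Il4ra, which encodes a chain of the IL-4 receptor. Il1rl1, which encodes the IL-33 receptor, had an intergenic peak at 16.4 kb. At the type 2 cytokine locus a single peak (chromosome 11, 53713692 to 53713864, row 2388 of 2537 in the file) lay between Rad50 and Il5. It held the DR1 match AGGTAAAAGGTTA at 53713705 to 53713717, with 2 mismatches, the most allowed. Its centre was 6.46 kb from the TSS of Rad50, to which it was assigned, 7.02 kb from that of Il5, 79.1 kb from Il13 and 95.1 kb from Il4, and these 3 cytokine genes had no peak assigned. Nor had Il17rb, the IL-25 receptor gene, Pparg itself (nearest peak at 602 kb), the TH1 regulator Tbx21 (148 kb) or Ifng (530 kb).

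**Figure D4:**
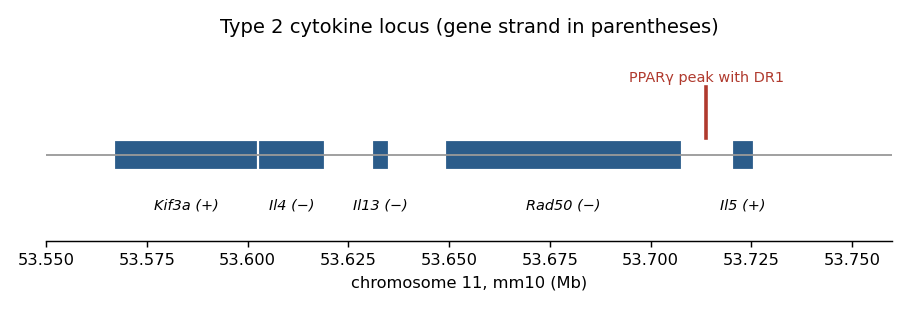
Map of the type 2 cytokine locus on chromosome 11 (x axis, mm10 position in Mb), with protein-coding genes as blue boxes, their strand in parentheses, and the PPARγ peak as a red line. The 1 peak of the region, at 53713692 to 53713864, lies in the intergenic sequence between Rad50 and Il5.

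TH17 and regulatory T cell genes also held peaks above expectation. The TH17 list had 11 of 26 genes (3.94-fold, adjusted permutation p = 0.00076), among them Il6st and Il6ra, which encode the IL-6 receptor chains, at 1.28 and 4.50 kb, and Fosl2 at 2.03 kb. Il17a had an intergenic peak with DR1 at 9.66 kb. Hif1a, a regulator of glycolysis and TH17 development, had 5 peaks, and the nearest, at 2.72 kb in an intron, held the exact DR1 consensus AGGTCAAAGGTCA (chromosome 12, 73905200 to 73905212). Nfkbiz, Irf4 and Tgfb3 had peaks at 16.5, 24.2 and 32.8 kb. The regulatory T cell list had 10 of 30 genes (3.44-fold, adjusted permutation p = 0.00127), with promoter peaks 78 bp from the cytokine subunit gene Ebi3 and 901 bp from Tnfrsf18, the latter with DR1. Further peaks lay at Ikzf2 (1.84 kb), the inhibitory receptor gene Pdcd1 (4.45 kb), Nrp1 (7.73 kb, with DR1) and Il10, which had 3 peaks, the nearest at 19.3 kb. The TH1 list had 5 of 32 genes (1.79-fold, adjusted permutation p = 0.395), among them Cxcr6, Irf8 and Prf1 at 8.06, 27.5 and 27.9 kb. In the test of the difference itself, 36.6% of TH2 genes and 15.6% of TH1 genes had a peak (log2 odds ratio 1.55, 95% interval −0.05 to 3.15, adjusted p = 0.194, Fisher's exact test). No difference passed the threshold against the TH17 list (−0.35, interval −1.82 to 1.13, exact adjusted p = 0.79) or the regulatory T cell list (0.37, interval −1.18 to 1.91, adjusted p = 0.79). The TH2 call was lost with peaks within 10 kb alone (adjusted permutation p = 0.075), and the TH2 and TH17 calls with DR1 peaks alone (adjusted p = 0.25 and 0.15).

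Genes of cytokine signalling inhibitors, T cell receptor signalling and migration formed further groups with peaks. The list of inhibitors of cytokine and inflammatory signalling, which also holds the TGF-β receptor gene Tgfbr2 and its transducer gene Smad3, had a peak at 19 of 39 genes (4.72-fold, adjusted permutation p = 0.00076). Among them were promoter peaks at the phosphatase gene Ptpn2 (431 bp) and the deubiquitinase gene Cyld (618 bp), and intergenic peaks at Socs3, a suppressor of cytokine signalling (1.13 kb), and Zfp36, which encodes an mRNA decay factor (2.91 kb, with DR1). Dusp5, Rgs1, Tnip1 and Socs5 had peaks at 7.12, 7.73, 9.02 and 11.4 kb, 4 of them at Rgs1. T cell receptor signalling genes had 14 of 39 (3.65-fold, adjusted permutation p = 0.00076), with intronic peaks in Themis (2.97 kb), the kinase gene Fyn (7.14 kb) and the adaptor gene Grap2 (15.7 kb), and peaks at Nfatc3 (4.53 kb) and Cd5 (20044 bp). Lcp2, the gene of the adaptor SLP-76, and the costimulatory receptor gene Cd28 had peaks with DR1 at 15.2 and 15.7 kb. This call was lost within 10 kb (adjusted permutation p = 0.24). Chemokine receptor and migration genes had 8 of 28 (3.41-fold, adjusted permutation p = 0.00868), including the gut homing receptor gene Ccr9 with an exonic DR1 peak at 1.43 kb. Others were the integrin genes Itgal (8.22 kb) and Itgb1 (93.2 kb), S1pr1 (46.8 kb), and Ccr1 with 3 peaks, the nearest at 28.0 kb. The migration call was lost within 10 kb, outside promoters, by gene body and with DR1 peaks alone (adjusted permutation p = 0.077, 0.082, 0.21 and 0.34).

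No list of another cell type or of ubiquitous machinery passed the threshold. B cell genes had 1 of 19 (0.803-fold), macrophage and dendritic cell genes 2 of 23 (1.02-fold), CD8 T and NK cell genes 1 of 20 (0.645-fold) and neuronal genes 2 of 30 (0.567-fold). Genes of innate type 2 cells, mast cells and eosinophils had 4 of 21 (2.24-fold, adjusted permutation p = 0.32). Ribosomal protein genes had 2 of 50 (0.842-fold) and oxidative phosphorylation genes 1 of 42 (0.459-fold). Glycolysis genes had 5 of 26 (2.38-fold, adjusted permutation p = 0.197): Myc, Hif1a, the hexokinase gene Hk2, the lactate transporter gene Slc16a1 and the glucose transporter gene Slc2a1. Nuclear receptor partners and coregulators of PPARγ had 6 of 32 (1.79-fold, adjusted permutation p = 0.347): Rara, the acetyltransferase genes Ep300 and Crebbp, Tbl1xr1, Nrip1 and Nr3c1, the glucocorticoid receptor gene. In all, 8 of the 19 lists held peaks above expectation and no list held fewer than expected past the threshold.

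**Figure D5:**
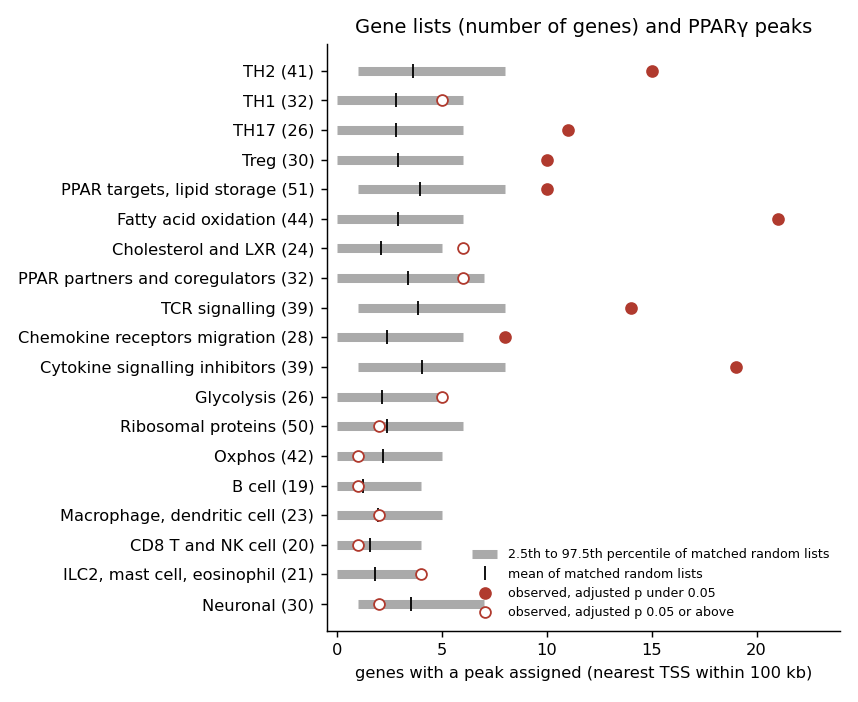
Number of genes with an assigned PPARγ peak (x axis) in each of 19 lists (y axis, with the number of genes), filled red where the adjusted p is under 0.05, over the mean (black tick) and central 95% range (grey bar) of 10000 matched random lists. Fatty acid oxidation stands at 21 genes against 2.88, and the B cell, macrophage and neuronal lists lie inside their ranges.

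The number of peaks per gene varied. Of the 1679 genes with a peak, 1347 had 1 peak, 332 had at least 2 and 8 had at least 5. Inpp4b, which encodes a phosphoinositide phosphatase, had 6 peaks within 100 kb of a start site. With 5 peaks each followed Plcl2, Hif1a, the adaptor gene Skap1, Bach2, a repressor that restrains effector differentiation, the Notch effector gene Rbpj, the OX40 ligand gene Tnfsf4, and Cytip. With 4 peaks, Lcp1, Plin2, Arap2, Capza2, Ets1, Fbxw7 and Slc44a1 stood nearest to their start sites, Lcp1, an actin bundling protein gene of leukocytes, at 527 bp. Within 100 kb, DR1 matches were found in 2 of the 5 peaks of Rbpj, in 2 of the 4 of Plin2 and in none of those of Plcl2, Skap1, Tnfsf4, Lcp1 or Ets1. Beyond that limit, an intronic peak of Plcl2 at 147934 bp and intergenic peaks nearest to Ets1 at 203577 and 328647 bp held DR1.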

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

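Chosen after the data were seen were the alternatives with the first 1268 or other 1269 peaks of the file, with DR1 peaks alone or removed, without chromosomes X and Y, and with sequence outside repeats. Of the main results, 155 alternative values kept their side of the threshold, 11 lost the call, 3 gained one and 5 counts moved. Of the other results, 305 kept their side, 26 lost a call, 8 gained one and 4 were counted as changes of sign. Values that turned sign with no call on either side count as kept. In log2 fold these include TH1 (0.74 to −0.12 within 10 kb), coregulators (0.75 to −0.02 by gene body), innate type 2 (0.98 to −1.39 within 10 kb), B cell (−0.22 to 0.43 within 10 kb) and cholesterol genes (1.33, values below). DR1 and AP-1 enrichment, the promoter, intron and intergenic shares and the fatty acid oxidation list kept their calls in each alternative run on them. The exon share passed below random with protein-coding genes alone (log2 fold −0.39) and outside repeats (−0.43). Against dinucleotide shuffles 1 motif was depleted in place of 2, YY1 turned to 0.28 and the KLF and SP site to 2.62. In the other 1269 peaks 16 motifs were enriched in place of 26 and DR4 turned to −0.22. With 1 mismatch 5 spacings were enriched and DR0 turned to −0.21. The following list calls were lost, given as log2 fold. Within 10 kb they were TH2 (1.52), T cell receptor signalling (1.204) and migration (1.57), leaving 5 lists above expectation in place of 8. By gene body they were lipid storage (1.06) and migration (1.10), and outside promoters migration (1.28). With DR1 peaks alone they were TH2 (1.38), TH17 (1.58) and migration (1.27), again leaving 5 lists; without DR1 peaks lipid storage (0.79), and without chromosomes X and Y lipid storage (1.11). Cholesterol genes gained a call without matching (1.47). They turned, without a call, to −1.35 within 10 kb (0 of 24 genes) and −0.18 in the first 1268 peaks (1 of 24). Fewer peaks enter the 10 kb and DR1 subsets; for the rest the cause was not tested. Values for the higher-scoring peaks and a test of score against DR1 were set out beforehand and not run, since the score is constant. No paired analysis was possible because there is a single ChIP library. Without replicates, nothing here measures how far the list would differ in another culture.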

Other observations

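Each test in this part was chosen after the main results were seen, except the DR1 share at T cell genes and the comparison with other cell types. Peaks at lipid genes and peaks at T cell genes differed in position and in sequence. Each peak was a unit in these tests, with 42 peaks from 31 lipid genes and 106 from 75 T cell genes. The tests were not matched on territory length, so its part in the difference in position is not known. The lists of lipid storage and fatty acid oxidation together had 42 peaks, a median of 2.90 kb from the TSS with 23.8% in promoters of any annotated transcript. The 7 T cell lists together had 106 peaks, a median of 24.5 kb away with 7.55% in promoters, and all 2124 peaks within 100 kb a median of 16.4 kb away with 9.04% in promoters. Both differences passed the threshold (distance adjusted p = 3e-05, permutation test; promoter share log2 odds ratio 1.90 ± 0.73 SE, adjusted p = 0.011, Fisher's exact test). A DR1 match was present in 50.0% of the lipid gene peaks (21 of 42) and 23.6% of the T cell gene peaks (25 of 106; log2 odds ratio 1.68 ± 0.55 SE, p = 0.00287, Fisher's exact test). AP-1 went the other way, with 1 of 42 lipid gene peaks (2.38%) and 22 of 106 T cell gene peaks (20.8%, beside 17.8% of all peaks within 100 kb; log2 odds ratio −2.88 ± 1.25 SE, exact adjusted p = 0.0069). Peaks of all other genes held DR1 in 19.8%, and no difference from the T cell lists passed the threshold (log2 odds ratio 0.34 ± 0.34 SE, exact p = 0.32).

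Across the whole list, no association of DR1 with AP-1 was found. AP-1 sites were present in 16.9% of the 502 peaks with DR1 and 18.1% of the 2035 without (log2 odds ratio −0.11, 95% interval −0.48 to 0.26, exact adjusted p = 0.94). In all, 85 peaks held both, 417 DR1 alone, 368 AP-1 alone and 1667 neither. Of 14 T cell factor sites compared in this way, the ROR site, which shares the AGGTCA core, was the only one to pass the threshold for going with DR1 (9.56% against 2.01%, exact adjusted p = 4.27e-12). The TSS of Gata3 was the nearest for 9 peaks, all on its downstream side: 1 at 11047 bp and 8 beyond the 100 kb limit, at 288588 to 913440 bp. Among the peaks on chromosome X, named after they were seen, were an intergenic peak with DR1 34.5 kb from Cd40lg, the gene of CD40 ligand, and an intronic peak with DR1 1.21 kb from Cysltr1, the gene of a cysteinyl leukotriene receptor.

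T cell genes held more peaks than matched random lists: 75 of 223 genes, 3.55-fold. B cell, myeloid, CD8 and NK, and innate type 2 genes together had 6 of 72 (1.08-fold, with permutation p = 0.00011 for the difference from T cell genes). No like excess was thus seen at genes of other cell types. This cannot tell why T cell genes held more peaks, since other cells would add peaks at their own genes. Nor does it cover other T cells, as genes shared with the T cell lists were left out. Capture of open T cell chromatin could not be judged, because no accessibility data were used here. DR1 was held by 23.6% of the peaks at T cell genes (exact 95% interval 15.9 to 32.8), against 2.53% of background windows. These peaks as a set therefore do not lack a PPAR element, but peaks of all other genes held DR1 in 19.8%. Such a share follows from the enrichment across the whole list and cannot tell why T cell genes held more peaks. Peaks without DR1 alone gave a 3.48-fold excess at T cell genes and those with it 4.49-fold, and the explanation stays open for both. Overexpression of the receptor may widen its binding, which a single library cannot test, and no biological explanation was tested.

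Chromosome X held 22 peaks. Repeats are argued against as the cause, since X had 0.253 peaks per Mb of sequence outside repeats and the autosomes 0.971 to 2.39. A low number of genes is argued against likewise, since X had 2.32 peaks per 100 protein-coding genes and the autosomes 7.07 to 19.1. A single copy of X per cell could lower tag counts towards the threshold of 8 tags, and the ratio to the autosomal median, 0.163, cannot be judged without tag counts for each peak. Both peaks on chromosome Y lay in repeats, and no biological explanation was tested.

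Peaks early in the file carried DR1 more often: 23.3% of the first 1268 and 16.2% of the others, with 32.0% in the first 250 rows and 12.4% to 23.2% in each later 250. A shift of GC content and promoter share along the file is argued against as the whole cause, since the mean position of DR1 peaks was −142 rows from that of all peaks and still −129 rows from that of their own GC and promoter strata (permutation p = 2e-05). Against peaks without the site, AP-1 and GATA peaks were also earlier (−198 and −111 rows, adjusted permutation p = 3e-05 and 0.0099), while ETS, RUNX and the scrambled DR1 did not pass the threshold (−84.8, −95.5 and 146 rows, adjusted p = 0.25, 0.20 and 0.195). An order by peak strength is a candidate explanation. The difference of −177 rows between peaks with and without DR1 cannot test it, since the rows hold no strength. The order does have a structure: among the named peaks, rows 1358, 1384, 1439 and 1482 lay on chromosomes 1, 4, 11 and 17, and row 1705 on chromosome 1 again. A sort on a value with many ties would leave such runs, but the rows do not say which value. Among the first 4 rows, named after they were seen, were peaks assigned to Hsd17b4, a gene of peroxisomal oxidation, Ccr9 and Socs1.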
